A study of Homo sapiens with 2 samples.

How the data were processed

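The series holds 2 libraries of IMR-90 cells, which are human lung fibroblasts. The NS library is the non-senescent control. The SEN library comes from cells that, per the labels, were exposed to 300 nM doxorubicin, a DNA-damaging topoisomerase poison, for 24 hours and then kept in culture for 9 further days. Nuclei were released with a nuclei isolation kit and libraries were made with a droplet kit for fixed RNA, per the labels' protocols. That kit reads RNA through pairs of gene-specific probes, so a gene without a probe gives no counts; the probe set is not given in the sources used here.

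The authors deposited whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, made with Cell Ranger 7.2.0, per the file headers. The genome build was GRCh38, per the submitters' processing notes. The deposited counts were not normalised. Tested on the files themselves, the matrices were not limited to called cells: they list 330689 barcodes for NS and 366479 for SEN, most of which hold fewer than 10 UMIs. How the authors selected cells for their own work is not given in the sources used here. Of the 37143 features, 542 carry an identifier marked as deprecated; these took 0.711% of NS and 0.686% of SEN UMIs and were left out of library sizes and comparisons. The remaining genes hold 20332026 UMIs in NS and 23512948 in SEN.

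Barcodes were kept by a rule fixed before the data were examined. A barcode needed at least the 99th percentile of the UMI totals of the 3000 largest barcodes of its library divided by 10, at least 500 UMIs, at least 300 genes with a UMI and under 10% mitochondrially encoded UMIs. The UMI limit came to 7586 in NS and 10442 in SEN. It left 191 NS barcodes and 88 SEN barcodes, after 3 SEN barcodes were removed for their mitochondrial share. They hold 9457665 and 9914785 UMIs, 46.5% and 42.2% of each library. Doublets were called with Scrublet in scanpy 1.11.5, which marked 9 barcodes in each library, and were kept except in an alternative.

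UMIs were summed over the kept barcodes of each library. The sums were scaled with the TMM method of edgeR 4.0.16 and are given as CPM. A log2 ratio adds a prior of 0.5 to each sum, and a gene was called measured with at least 100 UMIs over both libraries together. Each group is 1 library. There is therefore no test, and every difference lacks a replicate check. A size rule of 2-fold was used to count genes. Intervals are exact 95% Poisson intervals for a level, exact conditional binomial ones for a ratio and exact Clopper-Pearson ones for a share; all cover counting error only. A gene with 0 UMIs in a library has a fold given against a floor of 3 counts in that library, which is 0.336 CPM in NS and 0.286 CPM in SEN. Ratios and intervals were tested on simulated data for the comparison of SEN with NS. Counts were drawn from the mean of the NS and SEN profiles at the depth of each library, with 200 genes altered. Altered genes with enough UMIs entered among 10394 genes. Of 50 genes simulated 4-fold higher 100% lay beyond the size rule, of 50 simulated 1.5-fold higher 2%, and of 10200 unaltered genes 0%. The simulated counts were drawn per gene without barcodes, so these shares reflect counting error only. They do not cover UMIs gathered in few barcodes, and the 0% is not a rate of false calls for these data.

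Gene lists (22) and cell type marker lists (7) were fixed before the data were examined. For each list the median log2 ratio of its measured members is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. List symbols were resolved through a name table, since the files use older symbols for some genes (HIST1H1B, DDX58); 1 list symbol had no match. The genes named here were set by rule: the 15 genes highest and the 15 lowest in SEN by the bound of the counting interval nearest to a ratio of 1, the 4 members of each list farthest from 1 by that bound, and a fixed set of senescence genes and ligands. A few genes that these rules select are not given in the text, though list medians and counts include them. Other genes were named after their values were seen, as members of a described list. Chromosome positions come from a GENCODE annotation of GRCh38.

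Shares of barcodes were computed after thinning each barcode to 1000 UMIs, a depth that all kept barcodes reach. The background share is the one expected from 1000 draws of the profile of barcodes with 10 to 100 UMIs of the same library. Clusters were made within each library with scanpy (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 0.5). Alternatives covered the scaling (total counts, DESeq2 1.42.0 size factors, TMM without mitochondrial genes), the barcodes kept, doublets, the weight and depth of barcodes, free RNA, gene span, and the UMI minimum. The first 16 bases of a barcode name the gel bead and the rest names the library, which allowed the UMIs of both libraries to be set side by side for each gel bead. Counting used NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 under Python 3.11.15, with R 4.3.3.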

Results

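The data are probe-based single-nucleus RNA counts of IMR-90 human lung fibroblasts in 2 states, a non-senescent control (NS) and a culture made senescent with doxorubicin (SEN), with 1 library each. The kept barcodes held a median of 48676 UMIs in NS (191 barcodes) and 67473 in SEN (88 barcodes). The median number of genes with a UMI was 7365 and 8292. The deepest SEN barcode held 633667 UMIs, against 133811 in NS, and the 32 SEN barcodes above 100000 UMIs gave 77.8% of the summed SEN counts. In NS, 6 such barcodes gave 7.37%. As there was 1 library per group, no difference below has a replicate check and the intervals cover counting error only.

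The first question was how the treated cells differed from control across the transcriptome. Genes of cell division stood far lower in SEN, and most genes of the interferon response and 21 of 37 p53 targets stood at least 2-fold higher. MKI67, a marker of proliferating cells on chromosome 10 (128096659 to 128126385), was at 628 CPM in NS (95% interval 612 to 645) and 13.1 CPM in SEN (11.04 to 15.5). The complement gene C3 on chromosome 19 (6677704 to 6730562) was 194-fold higher in SEN (105 to 405), and the interferon-induced gene IFI6 on chromosome 1 (27666061 to 27672218) 63.2-fold higher (52.0 to 77.7). PAPPA, which encodes a secreted protease that cleaves insulin-like growth factor binding proteins, was at 18.9 CPM in NS and 592 CPM in SEN, a ratio of 31.3 (26.8 to 36.7). CCND2, a D-type cyclin, was at 5 UMIs in NS and 897 in SEN, a ratio of 152 (65.1 to 471). Of 10418 measured genes, 1035 were at least 2-fold higher in SEN and 1360 at least 2-fold lower, so that 43.2% of genes beyond the size rule were higher. Without barcodes above 100000 UMIs the numbers were 840 and 1613, or 34.2% higher, and with total counts in place of TMM 1336 and 1096, or 54.9% higher. Total counts shifted the median of all genes from -0.08 to 0.09 on the log2 scale, and ratios are given relative to the TMM value.

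Among the 15 genes highest in SEN, several were spread over many barcodes and several were not. PTCHD4 had 0 UMIs in NS and 146 in SEN, at least 41.4-fold higher against the floor of 3 counts per library, and OAS1 at least 32.9-fold higher (0 and 116 UMIs). FBXO32, a ubiquitin ligase subunit, had a ratio of 73.7 (28.5 to 272), CCN4 of 46.8 (30.5 to 75.9) and IFI44L of 194 (34.4 to 7686, with 1 UMI in NS). TNFSF15 had 1 UMI in NS and 324 in SEN, of which 43.2% lay in 1 barcode. All 229 SEN UMIs of PPP1R17, and all 124 of the chemokine receptor CXCR4, came from 1 barcode per gene, without which each gene was at 0 UMIs in both libraries. For LHX4, C9 and OR5B2, 1 barcode held 89.6%, 87.6% and 70.3% of the SEN UMIs. Among the 15 lowest genes, DLK1 had 115 UMIs in NS and 0 in SEN, at least 45.1-fold lower, and CDCA7 was 60.6-fold lower (23.3 to 225). The other 13 act in mitosis, the nuclear lamina or chromatin, among them NCAPH, KNL1, KIF14, KIFC1 and CENPE.

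Proliferation genes were lower in SEN as a block. All 52 measured genes of the G2 and mitosis list were at least 2-fold lower, with a median log2 ratio of -4.32 (percentile 0 of the matched random lists), and all 42 of the S phase list, with a median of -3.17 (percentile 0). Per gene, TOP2A was 27.5-fold lower (24.5 to 31.03), ANLN 32.5-fold (28.4 to 37.4), CENPF 30.2-fold (26.4 to 34.8) and the ribonucleotide reductase subunit RRM2 14.6-fold (12.4 to 17.3). CLSPN, DTL and CDC45, which act at replication forks, were 28.3-fold, 20.3-fold and 16.2-fold lower. What remained in SEN was uneven over barcodes: 1 barcode held 53.1% of the SEN UMIs of TOP2A, 56.5% of those of ANLN and 54.0% of those of KIF20A. Without the 2 SEN barcodes with the highest levels the list median was -5.56.

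Genes tied to the senescent arrest were mixed. CDKN1A, the p21 inhibitor of cyclin-dependent kinases on chromosome 6 (36676460 to 36687339), was at 19.3 CPM in NS and 263 CPM in SEN, a ratio of 13.6 (11.7 to 16.01). CDKN2B, encoding p15, had a ratio of 4.67 (2.88 to 7.95). CDKN2A, which encodes p16 and ARF, was low in both, 90 UMIs in NS and 84 in SEN, and its ratio of 0.793 (0.582 to 1.08) was not distinguishable from 1 at this depth. Lamin B1 (LMNB1), a nuclear lamina protein, was 48.1-fold lower in SEN (35.6 to 66.8) and HMGB2 12.9-fold lower (10.96 to 15.2). CDKN2C was 17.2-fold lower (11.6 to 26.7). HMGB1 was listed with 0 UMIs in both libraries. The whole list of 20 measured arrest and nuclear markers held 3 higher and 5 lower members, with a median of -0.26 (percentile 17.0).

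**Figure D1:**
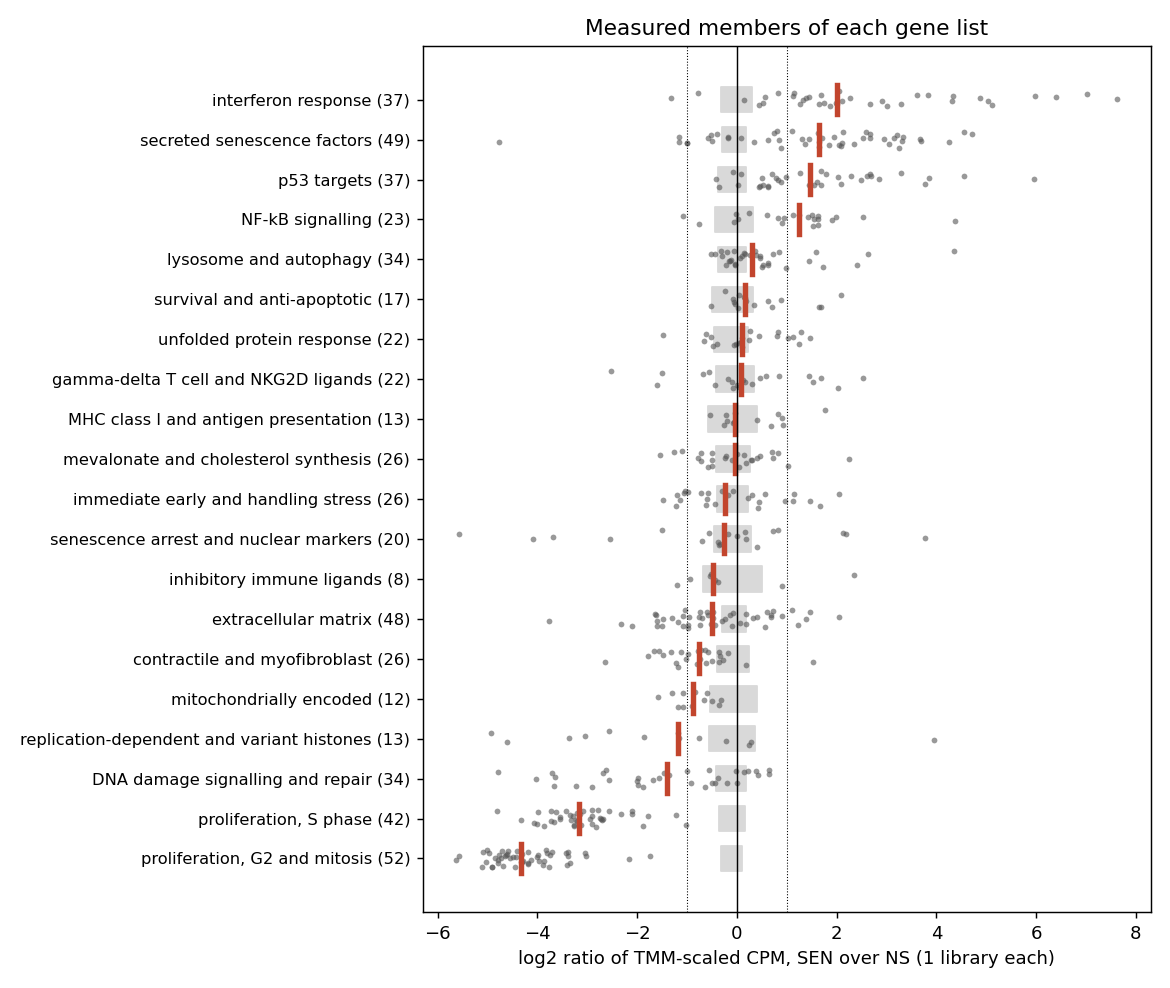
Log2 ratio of TMM-scaled CPM, SEN over NS (x axis), for each measured member (points) of each gene list (y axis, number of measured members in brackets). Red bars are medians, grey bands the central 95% of medians of 10000 matched random lists, and dotted lines mark 2-fold; the medians run from -4.32 for the G2 and mitosis list to 2.02 for the interferon list.

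The p53 target list was higher in SEN, with 21 of 37 measured members at least 2-fold higher, 0 at least 2-fold lower and a median of 1.47 (percentile 100). MDM2, the ubiquitin ligase that opposes p53, had a ratio of 4.90 (4.61 to 5.21), SPATA18 of 14.6 (10.1 to 22.1) and the stress cytokine GDF15 of 23.8 (18.2 to 31.6). TNFRSF10C, a decoy receptor for the death ligand TRAIL, had 2 UMIs in NS and 182 in SEN, a ratio of 77.3 (21.1 to 643). The DNA damage signalling and repair list went the other way, with 0 members higher, 19 of 34 lower and a median of -1.41 (percentile 0). BRCA2 was 16.3-fold lower (12.6 to 21.5), FANCD2 13.1-fold (9.805 to 17.9) and FANCA 12.7-fold (10.99 to 14.8); 2 list members, TOP2A among them, also stand in the proliferation lists.

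Secreted factors of senescent cells were mostly higher in SEN. Of 49 measured members 31 were at least 2-fold higher and 4 lower, with a median of 1.65 (percentile 100). IL6 was at 29.7 CPM in NS and 277 CPM in SEN, a ratio of 9.33 (8.23 to 10.6). The neutrophil chemokine CXCL8 had a ratio of 26.3 (21.1 to 33.3) and CXCL1 of 19.9 (10.9 to 40.3), with 38.3% and 51.8% of their SEN UMIs in 1 barcode. Among the lower members, the matrix protease MMP10 was 29.7-fold lower (12.4 to 92.9). The list median was 0.86 without barcodes above 100000 UMIs and 0.54 with barcodes thinned to 1000 UMIs, where fewer members reach the UMI minimum.

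Interferon response genes had a median of 2.02 (percentile 100), the highest of the lists in the main setting, with 30 of 37 members at least 2-fold higher and 1, CGAS, at least 2-fold lower. BST2, which tethers virions at the cell surface, had 1 UMI in NS and 149 in SEN, a ratio of 127 (22.4 to 5034). MX1 and OAS2 had log2 ratios of 5.04 and 5.11. The NF-kB signalling list had a median of 1.24 (percentile 100), with 13 of 23 members higher and 1, TNFAIP6, lower. In it, the adhesion molecule VCAM1 had a ratio of 20.9 (16.2 to 27.6), SOD2 of 3.97 (3.54 to 4.45) and CEBPD of 3.77 (3.07 to 4.67). The interferon median was 1.64 without doublets and 1.46 over every barcode, below the secreted factor medians of 1.81 and 1.72 there, and 1.19 without barcodes above 100000 UMIs.

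The series title concerns the targeting of senescent cells by γδ T cells, so ligands of these cells and of the receptor NKG2D were a fixed list. The list also holds adhesion molecules and death receptors. Its median of 0.09 lay inside the range of the random lists (percentile 75.3), and of 22 measured members 5 were at least 2-fold higher, 3 lower and 14 in between. The 5 higher members were ICAM1, an adhesion ligand of lymphocyte integrins, with a ratio of 5.79 (5.15 to 6.53), the death receptors TNFRSF10B with 4.07 (3.80 to 4.35), TNFRSF10A with 3.23 (2.32 to 4.58) and FAS with 2.72 (2.32 to 3.204), and the butyrophilin BTN3A3 with 2.91 (2.28 to 3.75). The death receptors also stand in the p53 target list, and ICAM1 in the secreted factor and NF-kB lists. Of the 5, BTN3A3 alone stands in no other list. BTN3A3 lies on chromosome 6 (26440472 to 26453415) and had 85 UMIs in NS and 291 in SEN. Its relatives BTN3A2 and BTN3A1 had ratios of 1.51 (1.21 to 1.90) and 1.18 (0.765 to 1.82), and BTN2A1, with BTN3A1 a part of phosphoantigen sensing by Vγ9Vδ2 T cells, of 1.03 (0.914 to 1.16). The NKG2D ligand MICA was at 60.1 CPM in NS and 83.0 CPM in SEN, a ratio of 1.38 (1.24 to 1.54).

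Other NKG2D ligands were near the limit of the depth. MICB had 9 UMIs in NS and 5 in SEN, ULBP1 had 3 and 12, RAET1G 2 and 7, and RAET1E 0 and 6. ULBP2 had a ratio of 1.10 (0.741 to 1.64) and ULBP3 of 0.675 (0.470 to 0.966). CD1D, which presents lipids, had 0 UMIs in NS and 13 in SEN, and APOA1 0 and 5. MR1, RAET1L, BTNL3, BTNL8, CD1A and CD1C were listed with 0 UMIs in both. Among the members lower in SEN were the mitochondrial chaperonin HSPD1 (3.04-fold, 2.82 to 3.27) and NECTIN1 (2.86-fold, 2.14 to 3.85). PVR and NECTIN2, ligands of the receptor DNAM-1, had ratios of 0.947 (0.879 to 1.02) and 1.005 (0.951 to 1.06). Ratios of others were 0.743 for EPHA2, 1.81 for PROCR, 1.11 for ANXA2, 0.936 for ANXA6, 0.881 for ATP5F1B, 0.622 for NCR3LG1 and 1.24 for CD58. The list median took either sign with the weight of barcodes, being -0.12 with equal weight and -0.39 without barcodes above 100000 UMIs. It also varied within SEN. In the 29 SEN barcodes under 0.5% mitochondrial UMIs, 13 of 18 measured members were lower than in the other 59, with a median log2 ratio of -0.52.

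**Figure D2:**
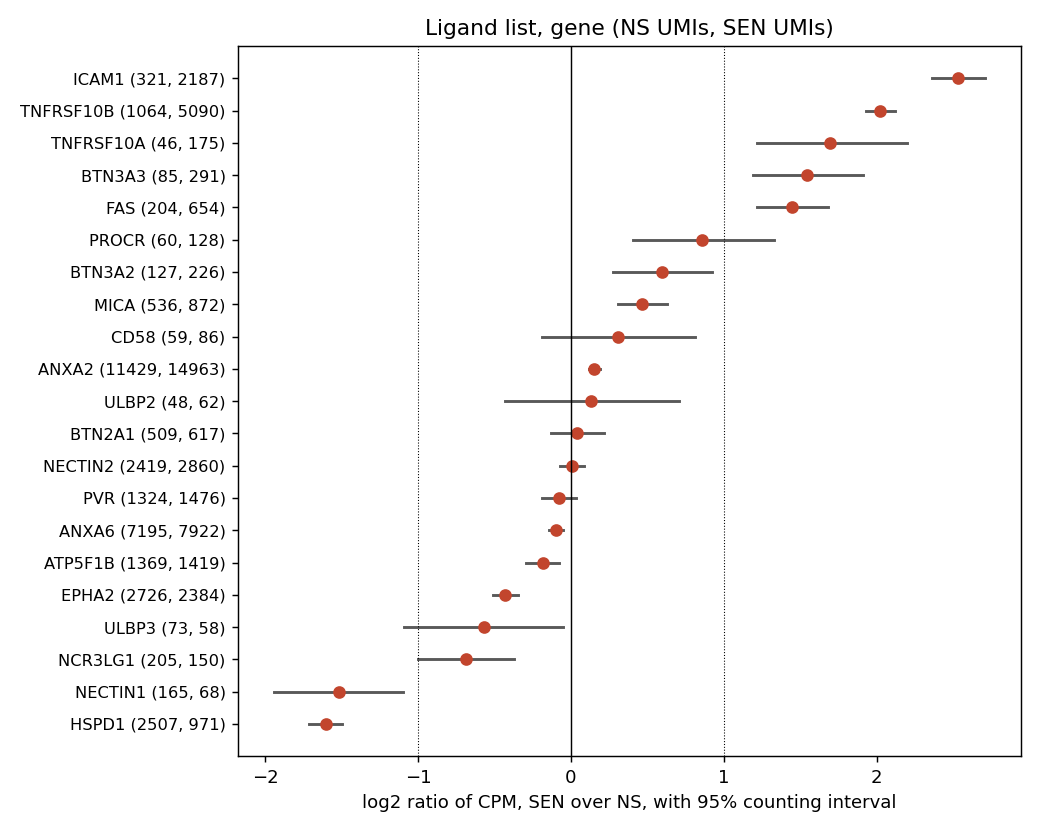
Log2 ratio of CPM, SEN over NS (x axis), of 21 of the 22 measured genes of the ligand list (y axis, NS and SEN UMIs in brackets), with exact 95% conditional binomial intervals for counting error only. ICAM1, TNFRSF10B, TNFRSF10A, BTN3A3 and FAS lie beyond the upper dotted line at 2-fold, and HSPD1 and NECTIN1 beyond the lower one.

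Mevalonate and cholesterol synthesis, the pathway that makes phosphoantigens, showed no common direction. The median of 26 measured members was -0.04 (percentile 59.95; 0.12 with total counts), with 2 higher and 3 lower. ABCA1, a cholesterol exporter, had a ratio of 4.76 (4.32 to 5.26), while ACAT2 and EBP were 2.90-fold and 2.14-fold lower. Of the MHC class I and antigen presentation list, with a median of -0.03 (percentile 57.9; 0.13 with total counts), TAP1 alone of 13 was beyond 2-fold, with a ratio of 3.43 (3.05 to 3.87). Beta-2 microglobulin (B2M) had 1.77 (1.69 to 1.86), TAPBP 1.91 and PSMB10 1.87. HLA-B, HLA-C and HLA-F were listed with 0 UMIs. Among 8 measured inhibitory immune ligands the median was -0.48 (percentile 9.18). CD274, encoding PD-L1, was 2.31-fold lower (2.03 to 2.64), with 34.7% of its SEN UMIs in 1 barcode, and VSIR was higher, with a ratio of 5.17 (3.37 to 8.23).

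The matrix and contractile lists had lower medians in SEN, with most members within 2-fold. The mitochondrially encoded share was lower too. Of 48 matrix genes 14 were at least 2-fold lower and 5 higher, with a median of -0.50 (percentile 0.03). COL5A3 was 13.7-fold lower (10.9 to 17.5), elastin (ELN) 4.99-fold (4.42 to 5.64) and periostin (POSTN) 4.30-fold (4.08 to 4.54), and the crosslinking enzyme LOXL4 had a ratio of 4.16 (3.37 to 5.18). Of 26 contractile genes 10 were lower and 1, ITGA11, higher, with a median of -0.75 (percentile 0.01). In it CDH2, encoding N-cadherin, was 6.24-fold lower (5.96 to 6.53), smooth muscle actin ACTA2 3.42-fold (3.15 to 3.72), CNN2 3.17-fold (2.94 to 3.42) and LRRC15 2.96-fold (2.67 to 3.28). The 12 mitochondrially encoded genes had a median of -0.87, with 5 lower, among them MT-ND1 (3.001-fold, 2.75 to 3.28). Beside these groups, the median mitochondrial share per barcode was 3.44% in NS (quartiles 2.78% to 4.23%) and 1.21% in SEN (0.227% to 2.70%). Among barcodes with 1 to 6% mitochondrial UMIs the matrix median was -0.20 and the contractile median -0.54; without barcodes above 100000 UMIs these were -1.15 and -1.21.

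Lists of cell type markers did not move together. The 15 fibroblast markers had a median of -0.14 (percentile 33.3; 0.03 with total counts), and the 4 measured epithelial markers, 3 of them keratins, -0.12 (0.05 with total counts). Smooth muscle or pericyte markers had a median of -1.49 (percentile 0.04), with CSPG4, MCAM, ABCC9 and CNN1 at least 2-fold lower. Of the endothelial list only FLT1 and TEK were measured, of the myeloid list CD68 and of the T or NK lymphocyte list IL7R; the list sums rose from 139 to 271 CPM for endothelial and from 42.2 to 97.48 CPM for myeloid markers and were 94.6 and 78.5 CPM for the lymphocyte markers. No B lymphocyte marker was measured.

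Per barcode, the libraries differed in the medians of the proliferation and p53 lists, with overlap of single barcodes. The median G2 and mitosis level was 8553 CPM in NS (quartiles 6167 to 13158) and 361 CPM in SEN (213 to 567). That of p53 targets was 1308 CPM in NS (1098 to 1711) and 4483 CPM in SEN (2956 to 5712). At 1000 UMIs per barcode, 180 of 191 NS barcodes (94.2%, 89.9% to 97.1%) and 8 of 88 SEN barcodes (9.09%, 4.01% to 17.1%) held at least 2 UMIs of the G2 and mitosis list. Unthinned, at median depths of 48676 and 67473 UMIs, the shares were 100% and 98.9%. The free RNA profile of the same library would give 99.9% and 38.0% at 1000 UMIs, so neither share exceeds background, and they are not read as shares of cycling cells. The NS barcodes formed 4 clusters of 64, 53, 30 and 44 barcodes, the second led by PIF1, TROAP and BORA and the fourth by ANKRD1, TNFRSF11B and EDN1. The SEN barcodes formed 2, of 27 and 61 barcodes, the first led by PDE4C, SLC25A45 and IQCN and the second by MMP1, CD248 and MT-ATP6, with median mitochondrial shares of 0.137% and 2.07%. No cluster was given a type; at resolution 1.0 the numbers of clusters were 7 and 5.

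**Figure D3:**
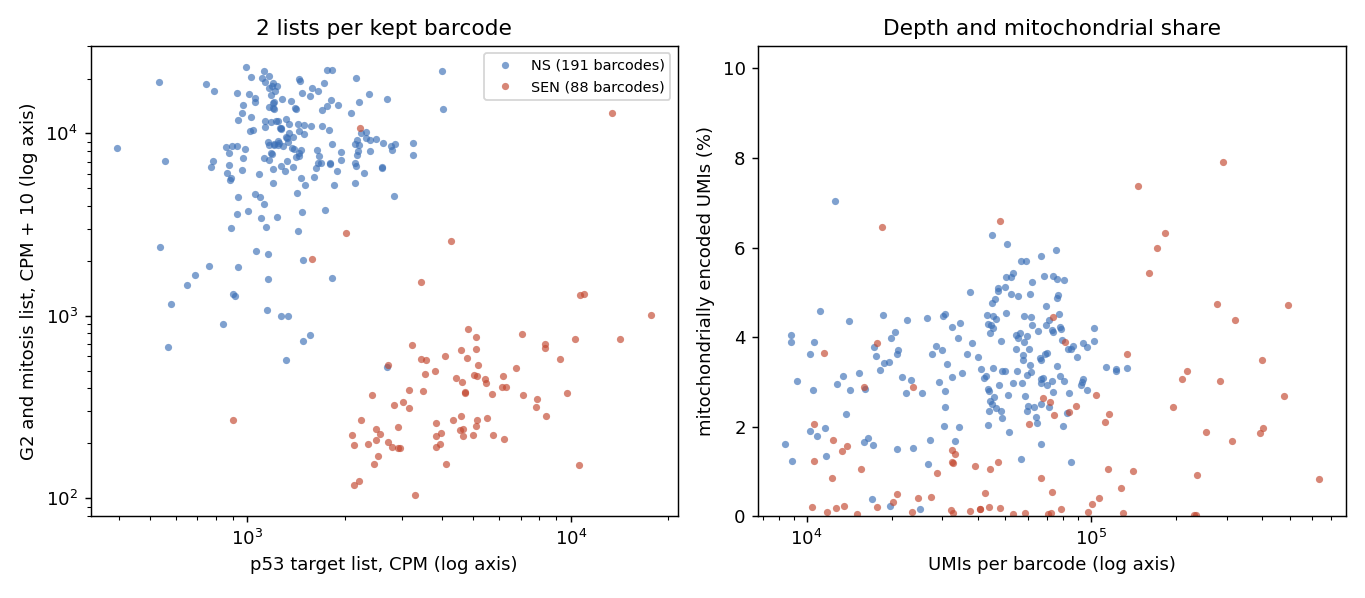
Left, G2 and mitosis list level (y axis, CPM + 10, log axis) against p53 target list level (x axis, CPM, log axis) for each kept barcode (points; 191 NS in blue, 88 SEN in red). Right, mitochondrially encoded share of UMIs (y axis, %) against UMIs per barcode (x axis, log axis); 29 SEN and 3 NS barcodes lie under 0.5%.

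The barcodes of both libraries could be set side by side for each gel bead, since the first 16 bases of a barcode name the bead. The kept NS barcodes shared their bead with a median of 378 SEN UMIs and the kept SEN barcodes with a median of 612.5 NS UMIs (quartiles 368 to 1361). Both libraries had a kept barcode on 10 beads. At least 500 UMIs were seen on 5710 beads in NS and on 6249 in SEN, and on 5397 in both.

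**Figure D4:**
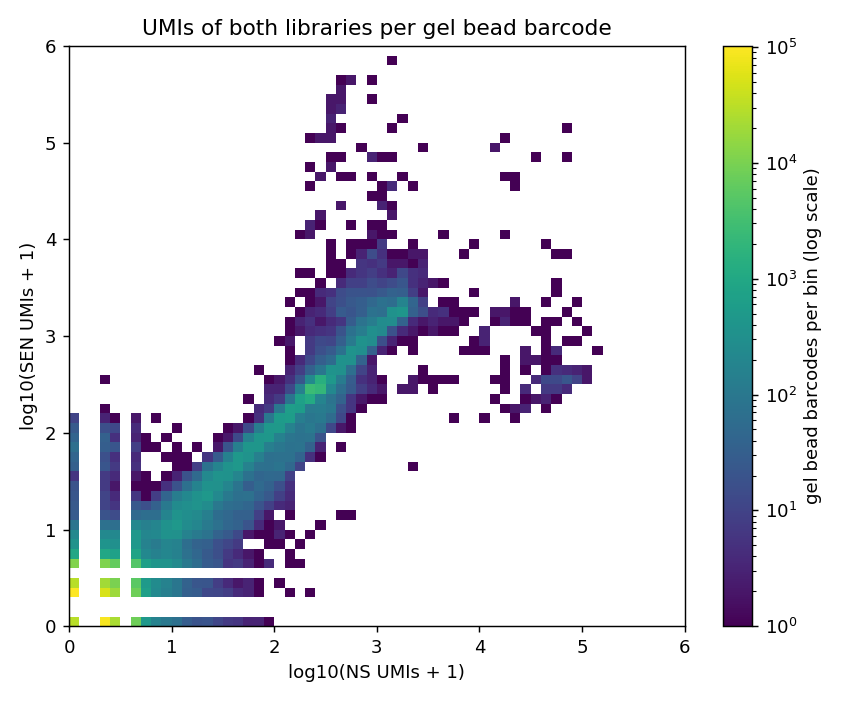
Number of gel bead barcodes (color, log scale) by their UMIs in NS (x axis, log10 of UMIs + 1) and in SEN (y axis, same scale). Beads with UMIs in both libraries lie mostly along a diagonal, the 5397 beads with at least 500 UMIs in both among them, and most kept barcodes lie off it towards the right and upper edges.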

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

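The tests of the barcodes with 500 to 5000 UMIs were chosen after the data were seen. Signals appeared in counts outside the comparisons. The 5508 NS and 6082 SEN barcodes with 500 to 5000 UMIs hold 28.7% and 34.1% of the UMIs and were not kept. Summed, they gave a median log2 ratio of -3.64 for the G2 and mitosis list and of 1.18 for the p53 target list, so that the contrast of the libraries was also present in them. Free RNA of a library would carry the same contrast. These barcodes therefore give no independent support for it, here or as an alternative setting. Among the features marked as deprecated, 199 had at least 100 UMIs, of which 13 were at least 2-fold higher and 35 lower in SEN.

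These barcodes outnumber the kept ones by far, and whether they are nuclei bears on how many cells the libraries hold. Separate nuclei of low RNA content would share gel beads about as often as independent placement gives. Yet 94.5% of the 5710 gel bead barcodes with at least 500 NS UMIs also held at least 500 SEN UMIs. Independent placement gives 73.5 over all 485694 gel bead barcodes, or 1555 over the 22946 with at least 100 UMIs in either library, against 5397 seen. Most of the 485694 are near empty, so 1555 is the stricter comparison. In NS the G2 and mitosis list varied over barcodes of 1000 to 2000 UMIs with a variance to mean ratio of 1.02, against 3.93 in kept barcodes and 1.01 in draws from the free RNA profile, so free RNA shared between droplets may account for them. In SEN 1 common profile is argued against as the whole source, since the matrix list had a ratio of 4.17 there, against 0.873 in draws and 1.19 in NS barcodes of that size. Lists differed within each library. In NS the matrix and mitochondrially encoded lists had 1.19 and 1.22, against 0.841 and 0.972 in draws. In SEN the mitochondrially encoded list had 2.46, secreted factors 1.52, the G2 and mitosis list 1.17, p53 targets 1.04 and interferon genes 0.994. What else the SEN barcodes hold, such as fragments of cells, stays open, and no biological explanation was tested.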

How the results depend on the processing

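Settings that left out barcodes above 100000 UMIs, used only barcodes with 500 to 5000 UMIs, took 1 to 6% mitochondrial UMIs, or left out top barcodes were chosen after the data were seen. Each of the medians of the G2 and mitosis, p53 target and secreted factor lists kept its sign in every setting that gave a value. The 98 genes set by the naming rules and beyond 2-fold kept their sign in all 1604 recomputations with enough UMIs, 36 of which came under 2-fold. That count leaves out genes that fell under the UMI minimum once their top barcodes were removed. PPP1R17 and CXCR4 had 0 UMIs there and gave no value. LHX4, C9 and OR5B2 had 21, 26 and 35 SEN UMIs left, OAS1 92 SEN UMIs and DLK1 91 NS UMIs, all under the minimum. The 98 genes were mostly chosen for large differences. Settings that changed only the scaling moved all log2 ratios by the same small amount. Those that changed only the UMI minimum per gene left the ratios of genes unaltered. Neither kind could change the sign of a gene beyond 2-fold, so the 1604 recomputations overstate how often the sign was tested. Over all genes beyond 2-fold, 7 higher genes changed sign without barcodes above 100000 UMIs, where 554 of 712 stayed at least 2-fold higher. At 500 to 5000 UMIs 3 higher and 4 lower genes changed sign, and at 1 to 6% mitochondrial UMIs 2 higher genes. Of all recomputed values of genes set by those rules and of lists other than the 4 below, 1616 stayed within counting error and 656 did not. Depth sets the counting error only, and with 1 library per group leaving out a replicate was not possible. Leaving out nuclei with any UMI of the G2 and mitosis list left 0 barcodes at full depth, so that alternative gave no value.

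The genes at least 2-fold higher numbered 1766 with a minimum of 20 UMIs and 451 with a minimum of 500, where those lower numbered 823; a stricter minimum tests fewer genes. Thinning to 1000 UMIs per barcode left 288 measured genes, 12 higher and 69 lower. The causes of the following shifts were not tested. The G2 and mitosis median was -4.16 with total counts, -4.15 for barcodes with at least 1000 UMIs, -3.90 over every barcode, -5.10 under 5% mitochondrial UMIs, -4.08 without doublets, -4.00 with equal weight, -4.58 thinned, -4.59 with free RNA subtracted, -3.88 without barcodes above 100000 UMIs, -3.64 at 500 to 5000 UMIs, -3.91 at 1 to 6% mitochondrial UMIs and -5.56 without the 2 SEN barcodes highest in these genes. The p53 target median was 1.64 with total counts and 1.18 at 500 to 5000 UMIs. The secreted factor median was 1.82 with total counts, 1.76 and 1.84 at minimums of 1000 and 2000 UMIs per barcode, 1.81 without doublets, 1.40 with equal weight, 0.54 thinned, 1.77 with free RNA subtracted, 1.86 and 1.44 at gene minimums of 20 and 500, 0.86 without barcodes above 100000 UMIs, 1.29 at 500 to 5000 UMIs and 1.92 at 1 to 6% mitochondrial UMIs. The ligand median was 0.25 with total counts, 0.23 at minimums of 1000 and 2000 UMIs per barcode, -0.12 with equal weight, -0.39 without barcodes above 100000 UMIs and 0.34 at 1 to 6% mitochondrial UMIs.

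The share of NS barcodes with at least 2 UMIs of the G2 and mitosis list was 99.4% among barcodes with at least 1000 UMIs, 89.2% without barcodes above 100000 UMIs, 79.6% thinned to 500 UMIs, 100% unthinned, and 97.4% and 88.0% with 1 and 3 UMIs required. The SEN share was 22.1% among barcodes with at least 1000 UMIs, 25% thinned to 2000 UMIs, 98.9% unthinned, and 34.1% and 3.41% with 1 and 3 UMIs required. Thinned settings that changed the barcodes or the depth drew their UMIs anew, and the counting interval does not cover the spread between draws. Leaving out barcodes above 100000 UMIs removed only 6 of 191 NS barcodes, too few to take the NS share from 94.2% to 89.2%. Most of that drop therefore comes from the new draw.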

Other observations

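The test of secreted factors by mitochondrial share and the random sets of NS barcodes were chosen after results were seen. So were the tests of residual cell cycle UMIs as NS material, which were read per barcode rather than over both barcodes together. The test of a loss of cytoplasm in nuclei isolation was set before. Other groups of genes showed members at odds with each other. In the list of histones, 8 of 13 measured members were at least 2-fold lower in SEN, with a median of -1.18 (percentile 0.01). The linker histones HIST1H1B and HIST1H1A were 30.7-fold and 25.6-fold lower and HIST1H1D 10.4-fold lower, whereas HIST2H2BE, an H2B gene, was higher with a ratio of 15.6 (11.4 to 21.9). The lysosome and autophagy list had a median of 0.31 (percentile 99.9), with 6 of 34 members higher and 0 lower; its median was -0.07 with equal weight per barcode. FUCA1, a lysosomal fucosidase, had a ratio of 21.3 (11.4 to 45.0), the protease CTSS of 6.35 (3.81 to 11.2), WIPI1 of 5.30 (4.47 to 6.33) and MAP1LC3B of 3.33 (2.91 to 3.82).

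In the unfolded protein response list (median 0.10, percentile 89.2; -0.12 with equal weight per barcode), ATF4 was 2.81-fold lower (2.45 to 3.22), while DDIT3, ERN1 and DNAJB9 had ratios of 2.38, 2.77 and 2.45. Immediate early genes had a median of -0.23 (percentile 18.3), with 5 higher and 6 lower; EGR1 had a ratio of 4.14 (3.89 to 4.41) and NR4A2 of 3.17, while MYC and FOSL1 were 2.79-fold and 2.32-fold lower. Genes of cell survival and death had a median of 0.16 (percentile 86.6; 0.33 with total counts and 0.35 with equal weight per barcode). The 3 of 17 that were higher all promote death: the BCL2 relatives BBC3 (4.25, 3.39 to 5.37) and BMF (3.28), and the caspase CASP9 (3.15). CFLAR, an inhibitor of death receptor signalling, had a ratio of 1.85 (1.71 to 2.01). All 53 ribosomal protein genes and all 20 nuclear-retained long noncoding RNAs were listed with 0 UMIs.

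The SEN barcodes were divided at a mitochondrial share of 0.5%. That limit has no gap around it, with single barcodes at 0.492% and 0.515%. Beside the other 59 SEN barcodes, the 29 under 0.5% had lower CPM of the matrix list (0.424 times), of secreted factors (0.354 times), of the lysosome list (0.4997 times) and of the ligand list (0.608 times). They had near equal CPM of p53 targets (1.13 times) and interferon genes (1.06 times). A loss of cytoplasm during nuclei isolation predicts the same difference in NS barcodes of low mitochondrial share. The 3 such NS barcodes differed in the same way in the matrix list, with a median log2 ratio of -1.91, and in secreted factors (0.317 times), and the difference had a correlation of 0.595 across 4151 genes with that in SEN; genes are not independent replicates. Not all lists agreed: in these NS barcodes p53 targets were 1.96 times and the G2 and mitosis list 1.29 times the CPM of the others, the latter against 0.743 times in SEN. The highest correlation over 1000 sets of 3 other small NS barcodes was 0.278, so a varying share of cytoplasm may account for these differences, while a separate senescent state was not tested. Less cytoplasm in SEN barcodes, which have the lower mitochondrial share, does not account for the higher secreted factors, since within SEN the median log2 ratio of that list in barcodes under 0.5% against the others was -1.45, with quartiles of -2.13 and -0.51.

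Residual division genes in SEN were uneven over barcodes. The barcode with the highest level held 12904 CPM of the G2 and mitosis list and the next one 10729 CPM, each above the NS median. Together they gave 47.3% of the SEN UMIs of the list. With the 5 highest barcodes the part was 55.1%, and the rest was spread over other barcodes. Unthinned, 87 of 88 SEN barcodes held at least 2 UMIs of the list. RNA of NS cells would bring a low p53 target level. The first barcode held 13389 CPM of p53 targets, above the upper quartile of SEN barcodes, which argues against NS material. The second held 2234 CPM, between the NS and SEN quartiles. Their gel beads held 2631 and 1753 NS UMIs. Both counts are under the 10000 set for NS material, a limit chosen after results were seen. Both are also above the upper quartile of 1361 NS UMIs over kept SEN barcodes. The second barcode held 171405 UMIs in all, more than any kept NS barcode, which goes against NS material. Its p53 target level is nearer the NS median than the SEN one, so for this 1 barcode a cycling treated cell and a misplaced NS cell cannot be told apart. Scrublet marked neither barcode as a doublet, which does not exclude one, and what the first barcode is stays open.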
